A study of Homo sapiens with 6 samples.

How the data were processed

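RNA from cultured human intrahepatic biliary epithelial cells (HiBEC) was sequenced in 6 samples, 3 treated with the vehicle DMSO and 3 with SGC-CBP30. The deposited table holds 1 count per gene and sample for 64253 rows, with a gene identifier, a symbol, coordinates and a length. Reads were aligned with TopHat2 2.1.0 to GRCh38 and counted with featureCounts, per the submitters' processing notes, which also name edgeR without saying for which step. The authors deposited these counts without normalization, as the values show: they are whole numbers and sum to between 38898263 and 56867256 per sample. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here.

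The counting affects some genes more than others. FTH1 had 1156217 counts over the 6 samples and BEST1, whose gene model overlaps it, had 891712, and 2 rows named TUBB3 had 30931 and 30078. Reads in an overlap therefore appear to enter the count of both genes, and values for genes that overlap a neighbour (KRT8 and KRT18, ACTA2 and FAS, histone genes with long models, TUBB3) are uncertain to that extent. Without a stated strand setting, a gene and an antisense partner cannot be told apart, and genes with near-identical copies may have lost or gained reads. Another 4146 rows lie on alternate contigs and were left in the table.

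Samples were grouped by the agent the labels give, and the replicate numbers come from the sample descriptions. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates looked like 1 library deposited again: chi-square statistics per degree of freedom between replicates ran from 5.27 to 17.8, where sampling noise alone gives about 1.

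Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, group as the only term) after TMM normalization. The edgeR filter on low counts (filterByExpr with its default minimum of 10 counts) left 20252 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. The standard error (SE) of a log2 fold change was computed as its size over the square root of the F statistic. CPM values, the counts scaled to a common library size, use the TMM-scaled library sizes and are given as mean ± SD over 3 samples. The count of 3 that a result of 0 allows corresponds to 0.0558 to 0.0783 CPM, depending on the library, and covers counting error only.

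The 24 gene lists and the rule for naming genes were fixed before the data were examined, and all 501 list entries were matched to a row, 19 of them under an older symbol. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry were alternatives. The rule named EP300 and CREBBP; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups; for each list the 3 members with the smallest adjusted p in the direction most members took, at a mean of at least 1 CPM (1 member in each direction where the counts tied); and FN1, CCN2, CDKN1A, CDKN2A, IL6, CXCL8, KRT7, KRT19 and SOX9. With a further gene these came to 82, a few of which are not reported here. Other list members are named as examples chosen after their values were seen.

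The edgeR step was tested on simulated counts for SGC-CBP30 against DMSO over 20024 genes, with 200 of them changed. The changed genes were drawn from those with a mean of at least 1 CPM. The step called 77.6% (52) of the genes changed 1.5-fold, 92.5% (62) of those changed 2-fold and 100% (66) of those changed 4-fold. Beside these it called 14 of 19824 unchanged genes. The rates do not cover scarcer genes, and the simulated share of changed genes was far below the 25.7% of the data. Alternatives were RLE scaling, total counts alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, the edgeR exact test, a stricter threshold, a 2-fold limit, leaving out each library and a block for the replicate number. Alternatives added after the data were seen were a covariate for the level of ALB, AFP, APOB and TF and a count that leaves out genes with an excess in SGC-CBP30 library 3. Principal components used the 500 most variable genes. Genes whose level would show the sex of a donor were left out of the text and of the comparison of SGC-CBP30 library 3 with the other treated libraries.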

Results

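HiBEC are human biliary epithelial cells, the cells that line the bile ducts inside the liver (cholangiocytes), used at passages 4 to 6. They were starved of serum for 4 h and then given 10 µM SGC-CBP30 for 24 h. SGC-CBP30 is a small molecule that binds the bromodomains of the histone acetyltransferases CBP and p300, and the stated purpose was to see how gene expression changes when p300 is inhibited. The vehicle group (DMSO) had 3 samples with 38898263, 49062218 and 56867256 counts, and the SGC-CBP30 group had 3 samples with 42986658, 42695601 and 45455043. The fibronectin gene FN1 and the collagen genes COL1A1 and COL1A2 were the most abundant transcripts. They took 8.87% to 9.87% of all counts in DMSO and 6.37% to 7.21% in SGC-CBP30.

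After SGC-CBP30, most measured genes of the extracellular matrix, interferon and ATF4 lists were lower and most of the histone list were higher. With an estimated correlation these 4 list calls were lost (adjusted p = 0.249 for the matrix list and adjusted p = 0.251 for the others). Among genes with a mean of at least 5 CPM and no overlap between the groups, as the naming rule requires, the deepest falls were in the interstitial collagenase gene MMP1 (10.4-fold lower), the matrix proteoglycan gene ASPN (8.21-fold), the smooth muscle gene CNN1 (7.86-fold), the cell adhesion gene NTM (7.07-fold), the NAD synthesis gene NMNAT2 (6.23-fold) and the galactosyltransferase gene B3GALT2 (5.55-fold). Under the same rule the largest rises were in the hepatic genes ALB, APOB, TF and AFP (24.9-, 19.9-, 16.2- and 15.0-fold, values that depended on DMSO replicate 2, without which the log2 fold change of ALB was 8.01 in place of 4.64), then in REEP2, which encodes a membrane-shaping protein (3.53-fold), and the histone gene H2BC5 (2.73-fold). MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160 in GRCh38) fell from 24.1 ± 3.64 CPM to 2.30 ± 0.411 CPM (SD, n = 3), a log2 fold change of -3.38 with SE 0.138 and an edgeR adjusted p of 8.33e-11. In all, 5207 of 20252 tested genes (25.7%) changed, 2314 higher and 2893 lower, and 992 of them changed at least 2-fold, 234 higher and 758 lower. The median size of the change among the changed genes was 0.44 on the log2 scale. The groups did not overlap in CPM for 39.4% of tested genes, where chance gives 10%. The first principal component held 77.8% of the variance and separated the groups. Pearson's r across genes was 0.991 to 0.993 within groups and 0.977 to 0.982 between them (genes are not independent replicates). Of the 82 genes taken by the rule, 79 had all 3 SGC-CBP30 libraries on one side of all 3 DMSO libraries, the exceptions being CDKN2A, IL6 and CXCL8; the rule mostly takes genes with no overlap or a small adjusted p, so this separation follows largely from the selection. Scaling by total counts alone raised the number of higher genes to 4384 and their share of the calls from 44.4% to 66.7%. With the summed level of 4 hepatic transcripts as a covariate, an alternative added after seeing the data, 1174 genes passed. That level does not overlap between the groups, so the covariate takes up part of the treatment term. A call lost with it can go with a larger log2 fold change (EP300, 0.347 in place of 0.236) or a smaller one (NLRC5, -0.289 in place of -0.515).

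The genes of the compound's targets were slightly higher in treated cells. EP300, which encodes p300, measured 99.1 ± 6.75 CPM in DMSO and 116.8 ± 4.84 CPM in SGC-CBP30 (log2 fold change 0.24, SE 0.0648, adjusted p = 0.0127). CREBBP, which encodes CBP, measured 98.7 ± 8.82 and 119.8 ± 8.73 CPM (0.28, SE 0.0734, adjusted p = 0.010). Both calls were lost when DMSO replicate 2 (adjusted p = 0.0525 for EP300 and 0.0615 for CREBBP) or SGC-CBP30 replicate 2 (0.0683 and 0.0654) was left out, and that of EP300 also with the hepatic covariate (0.121). Of the 18 CBP/p300, BET and HDAC genes, 8 rose and 3 fell, with the same counts adjusted over the list alone. HEXIM1, an inhibitor of the elongation factor P-TEFb, rose by 0.41 on the log2 scale, the acetyltransferase gene KAT2B by 0.48 and the bromodomain gene BRD2 by 0.35, while the class II deacetylase gene HDAC9 fell by 0.95. The list as a whole did not pass (camera adjusted p = 0.0807), though it did without SGC-CBP30 replicate 3 (0.0411).

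Genes of the TGF-beta response and extracellular matrix fell together. Of 29 measured members, 24 fell and 2 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.77 (camera adjusted p = 2.75e-12). With an estimated correlation the list's adjusted p = 0.249. ACTA2, the actin of smooth muscle and myofibroblasts, fell 3.05-fold, from 192.4 ± 4.13 to 63.1 ± 1.39 CPM (adjusted p = 3.97e-11). TAGLN, an actin-binding protein gene, fell 2.51-fold and LOX, which crosslinks collagen, 2.58-fold. CCN2 (connective tissue growth factor) fell from 407.5 ± 20.6 to 215.2 ± 10.4 CPM. FN1 fell 1.51-fold, from 44850 ± 2220 to 29730 ± 1650 CPM (log2 fold change -0.59, SE 0.0700, adjusted p = 8.85e-06). The 2 members that rose were the metalloproteinase inhibitor genes TIMP1 (log2 fold change 0.49) and TIMP3 (0.33). LOXL2 (0.051), CCN1 (0.015) and TGFB1 itself (-0.017) did not pass the test.

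**Figure D1:**
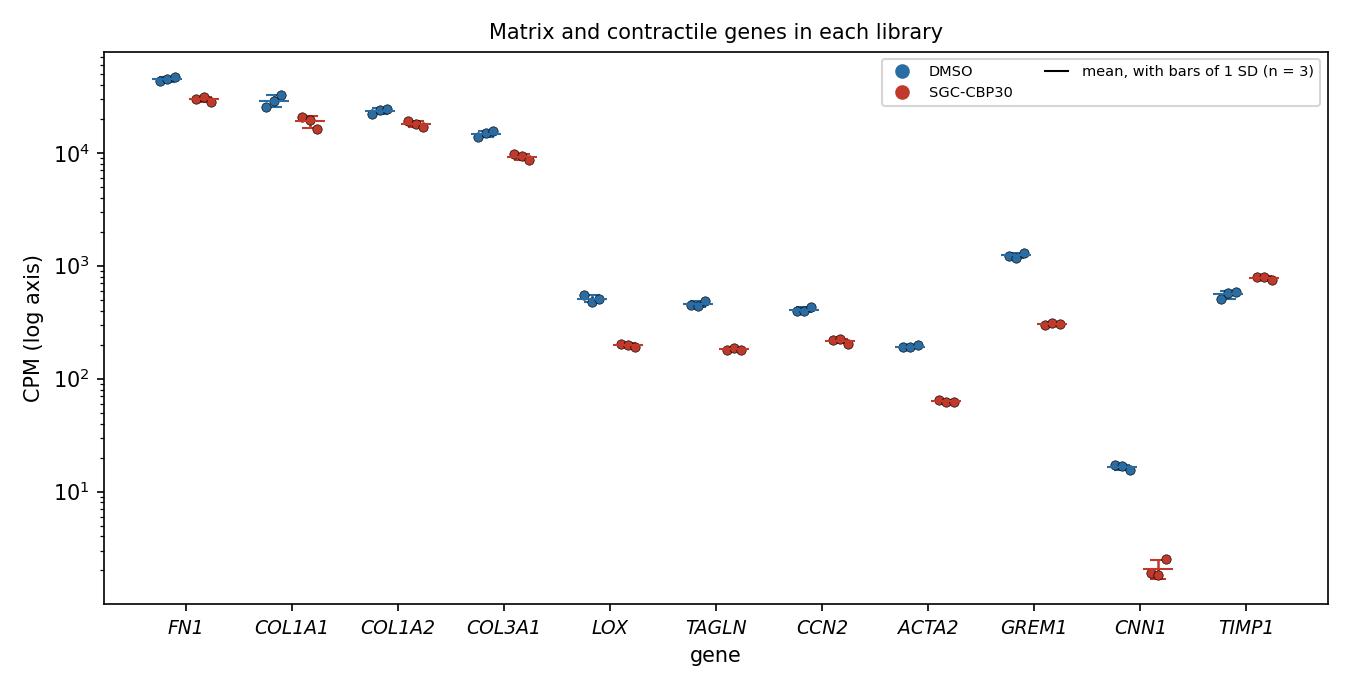
CPM of 11 matrix and contractile genes in each library, on a log axis; points are the 3 DMSO (blue) and 3 SGC-CBP30 (red) libraries, with the mean and bars of 1 SD. For each of the 10 genes shown that fell, the SGC-CBP30 libraries lie below all DMSO libraries (ACTA2 means of 192.4 and 63.1 CPM), and for TIMP1 they lie above (556.4 and 780.4 CPM).

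Markers of fibroblasts and stellate cells, the matrix-producing cells of the liver, were abundant in these cultures and mostly fell. Of 13 measured markers 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00192, and adjusted p = 0.249 with an estimated correlation). The proteoglycan genes DCN and LUM fell from 1646 ± 28.3 to 729.4 ± 19.5 CPM and from 653.5 ± 31.9 to 333.4 ± 31.2 CPM, and the fibroblast protease gene FAP fell by 1.12 on the log2 scale. The surface marker THY1 rose by 0.55, and the receptor gene PDGFRB, at 970.8 ± 51.9 and 930.3 ± 93.0 CPM, did not pass. YAP/TEAD targets also fell, 15 of 22 over all genes and 17 of 22 adjusted over the list alone, where AMOTL2 alone passed in the other direction (camera adjusted p = 3.31e-07, and adjusted p = 0.249 with an estimated correlation). IGFBP3, which binds insulin-like growth factors, fell 3.28-fold, CCN2 1.89-fold and NT5E, the ecto-nucleotidase CD73, by 0.88 on the log2 scale. All 10 measured endothelial markers fell, with the same count adjusted over the list alone, from low levels (camera adjusted p = 1.37e-05, and adjusted p = 0.249 with an estimated correlation). The angiopoietin receptor gene TEK measured 16.2 ± 0.618 CPM in DMSO and 5.63 ± 0.691 CPM in SGC-CBP30, ROBO4 3.66 ± 0.178 and 0.683 ± 0.196 CPM, and EMCN 1.98 ± 0.371 and 1.04 ± 0.130 CPM.

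Interferon-stimulated genes were lower in treated cells, while inflammatory factors went both ways. Of 30 interferon-stimulated genes 22 fell and 8 did not pass, and 23 fell when adjusted over the list alone (camera adjusted p = 2.64e-09, and adjusted p = 0.251 with an estimated correlation). XAF1 fell 2.06-fold, from 83.6 ± 11.7 to 40.6 ± 4.96 CPM. The antiviral synthetase gene OAS1 fell by 0.83 and the GTPase gene GBP1 by 0.69 on the log2 scale. IRF1, a transcription factor gene of the list, did not pass (-0.14, adjusted p = 0.122). In antigen presentation 3 of 16 genes fell, the peptide transporter gene TAP1 (-0.39), the HLA class I regulator NLRC5 (-0.52) and the immunoproteasome gene PSMB8 (-0.27). Adjusted over the list alone 3 rose and 5 fell (camera adjusted p = 0.468), and the fall of PSMB8 was lost with total counts alone (adjusted p = 0.0652) and without SGC-CBP30 replicate 3 (0.0571). With the hepatic covariate the falls of TAP1 (0.106), NLRC5 (0.439) and PSMB8 (0.606) were all lost. Of 28 genes of NF-kB and secreted inflammatory factors 11 fell and 7 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0858). MMP1, the cytokine gene IL11 (-1.84) and the NF-kB inhibitor TNFAIP3 (-0.64) fell, while another NF-kB inhibitor, NFKBIA (0.45), and the chemokine gene CXCL1 (0.38) rose. IL6 measured 20.3 ± 2.36 and 18.2 ± 0.533 CPM (adjusted p = 0.224). CXCL8 measured 253.7 ± 42.4 and 210.0 ± 21.4 CPM, just past the threshold (adjusted p = 0.0499), and lost the call without DMSO replicate 1 (0.263), SGC-CBP30 replicate 1 (0.203) or SGC-CBP30 replicate 2 (0.144), and with DESeq2 (0.263), limma-voom (0.0568), the robust fit (0.0704), total counts alone (0.194), the replicate block (0.0954) and the hepatic covariate (0.125). The list passed without DMSO replicate 2 (0.0447) or SGC-CBP30 replicate 3 (0.0429).

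Most stress-response genes of the ATF4 and unfolded protein response list fell, while more p53 targets stayed short of the threshold than fell. In the first list 16 of 21 genes fell and 1 rose, or 2 rose adjusted over the list alone (camera adjusted p = 1.32e-05, and adjusted p = 0.251 with an estimated correlation). The cystine transporter gene SLC7A11 fell from 99.7 ± 11.8 to 52.96 ± 4.38 CPM, the pseudokinase gene TRIB3 by 0.68 and the stress sensor gene ERN1 by 0.64 on the log2 scale. The endoplasmic reticulum chaperone gene HSPA5 (0.024, adjusted p = 0.821) did not pass, and HYOU1, a chaperone of the same compartment, rose by 0.23. Of 24 p53 targets and CDK inhibitors 11 fell and 13 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 6.66e-04, and adjusted p = 0.251 with an estimated correlation). The death receptor gene FAS fell by 0.51, GDF15 by 0.66, GADD45A by 0.50 and the CDK inhibitor gene CDKN1A by 0.32 on the log2 scale. FAS overlaps ACTA2 in the coordinates of the table. CDKN2A measured 11.2 ± 1.36 and 12.5 ± 1.45 CPM (adjusted p = 0.367).

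Cell cycle genes did not move as a group. Of 26 genes for mitosis 7 fell, among them the kinesin genes KIF23 (-0.81) and KIF20A (-0.80) and the spindle gene ASPM (-0.58), and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.203, or 0.0339 without SGC-CBP30 replicate 3). The proliferation marker MKI67 measured 3.16 CPM in DMSO and 2.59 CPM in SGC-CBP30 (adjusted p = 0.254). Of 26 genes for DNA replication and S phase 4 rose, including MCM3 (0.30), MCM6 (0.28) and RRM1 (0.21), and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.468). RRM1 did not pass without DMSO replicate 2 (adjusted p = 0.106) or without any one of the SGC-CBP30 replicates (0.0599 to 0.0694), nor with the replicate block (0.0794) or the hepatic covariate (0.483).

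Biliary markers went in both directions, and several were barely detected in the vehicle cultures. Of 19 measured cholangiocyte and biliary epithelium genes 5 fell and 4 rose, or 5 and 5 adjusted over the list alone. The median log2 fold change was -0.065, the mean 0.15 and the camera direction down (adjusted p = 0.542). KRT7, a keratin of the bile duct epithelium, fell 3.70-fold, from 29.2 ± 5.05 to 7.89 ± 0.865 CPM (log2 fold change -1.89, SE 0.118, adjusted p = 6.62e-09). SPP1 (osteopontin) fell 4.59-fold, KRT19 from 3.45 ± 0.722 to 2.09 ± 0.436 CPM and the transcription factor gene SOX4 by 0.46 on the log2 scale. SOX9, a biliary transcription factor gene, rose from 3.88 ± 0.459 to 5.53 ± 0.146 CPM. The fall of KRT19 was lost without SGC-CBP30 replicate 1 (adjusted p = 0.0507) and with the hepatic covariate (0.269). The rise of SOX9 was lost with that covariate too (0.32). The epithelial adhesion genes EPCAM and CDH1 rose from 0.0953 ± 0.115 to 0.487 ± 0.177 CPM and from 0.199 ± 0.223 to 0.867 ± 0.423 CPM, and CFTR had 0 counts in all 6 libraries. The surface marker CD24 had the list's largest rise (3.45), from 0.128 ± 0.137 to 1.496 ± 0.668 CPM. CDH1 had 6, 21 and 0 counts in DMSO libraries 1, 2 and 3 and 30, 25 and 64 in SGC-CBP30 libraries 1, 2 and 3, highest in DMSO library 2 and SGC-CBP30 library 3, as the hepatic gene ALB was; EPCAM had 0, 3 and 12, and 13, 28 and 25.

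Most hepatocyte markers were scarce in the vehicle libraries and higher in the treated ones. Of 11 measured markers 9 rose, with the same count adjusted over the list alone, and the median log2 fold change was 4.02 (camera adjusted p = 1.82e-05, and adjusted p = 0.257 with an estimated correlation). ALB, the gene of serum albumin, had 7, 166 and 4 counts in DMSO libraries 1, 2 and 3 and 951, 1032 and 2337 in SGC-CBP30 libraries 1, 2 and 3. AFP (alpha-fetoprotein) had 12, 175 and 28 counts in DMSO and 716, 697 and 1738 in SGC-CBP30. The protease inhibitor gene SERPINA1 measured 1.37 ± 0.585 and 8.57 ± 2.63 CPM and the apolipoprotein gene APOA2 0.0961 ± 0.136 and 2.55 ± 1.24 CPM. The fold change depended on DMSO replicate 2: without it the log2 fold change was 8.01 in place of 4.64 for ALB, 7.72 in place of 4.32 for APOB, 6.69 in place of 4.02 for TF, 5.72 in place of 3.91 for AFP and 6.71 in place of 4.64 for APOA2. Without DMSO replicate 3 it was 4.00 for ALB, 3.73 for APOB and 3.42 for TF. SGC-CBP30 library 3 exceeded both other treated libraries by over 1.5 times in 53 of the 118 genes raised by more than 1.5 on the log2 scale, against 5 of 2192 compared genes raised by less and 42 of 349 genes lowered by more than 1.5. APOB with DESeq2 (adjusted p = 0.0543) and TF with the robust fit (0.0551) lost their calls. Of the 5 measured immune cell markers 1 rose and 2 fell, with the same counts adjusted over the list alone; the median log2 fold change was -0.47, the mean 0.21 and camera's adjusted p = 0.452. LYZ (lysozyme) rose from 0.0475 ± 0.0246 to 1.42 ± 0.762 CPM, and the macrophage genes CD68 (-0.47) and CD163 (-2.67) fell. LYZ had 1, 2 and 4 counts in DMSO libraries 1, 2 and 3 and 37, 50 and 108 in SGC-CBP30 libraries 1, 2 and 3. As for ALB, SGC-CBP30 library 3 was the highest, but DMSO library 2 was not the highest DMSO library.

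**Figure D2:**
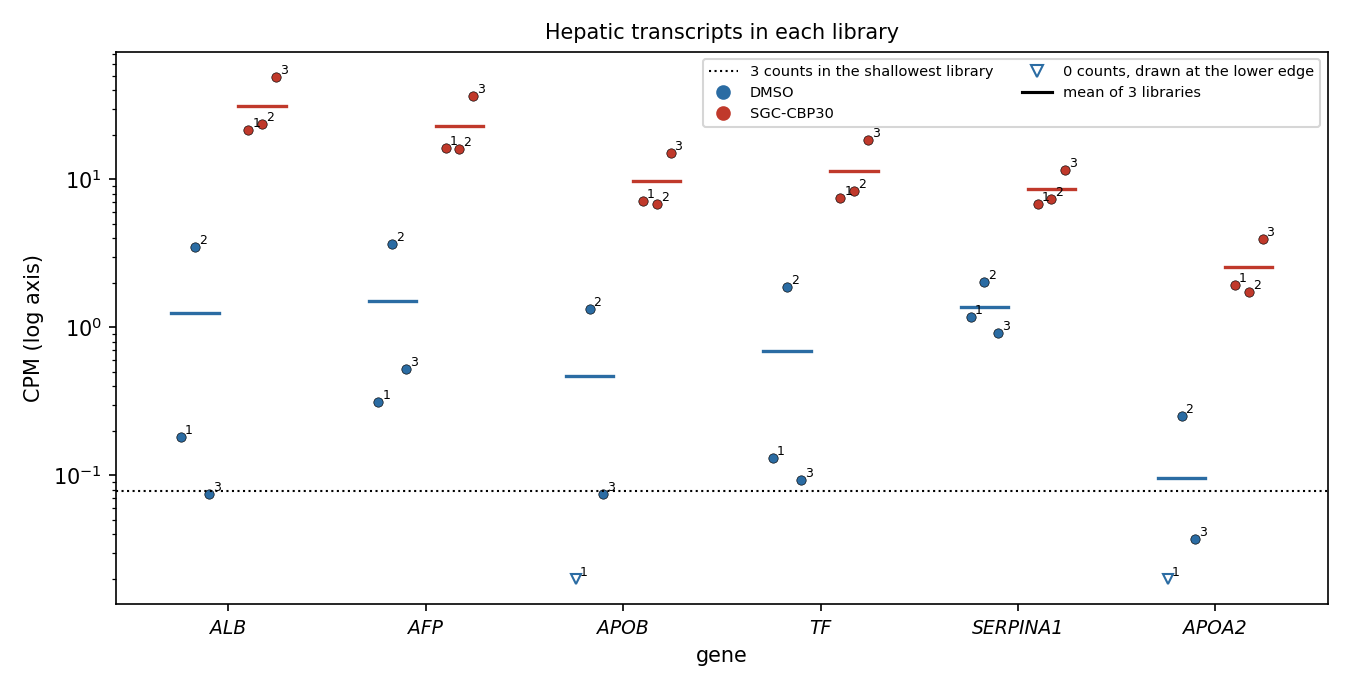
CPM of 6 hepatic genes in each library, on a log axis; points are libraries (blue DMSO, red SGC-CBP30), the numbers beside them are replicates, horizontal bars are means and open triangles mark 0 counts. SGC-CBP30 library 3 lies highest for each gene and DMSO library 2 lies above the other DMSO libraries (166 ALB counts against 7 and 4).

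Most polyadenylated histone genes rose, while most targets of the Notch, Wnt and Hedgehog pathways did not pass the test. Of 13 histone genes 8 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.91e-04, and adjusted p = 0.251 with an estimated correlation). H2BC21 rose from 11.2 ± 0.299 to 29.3 ± 2.78 CPM, H2BC5 from 5.22 ± 0.350 to 14.2 ± 0.961 CPM and H2AC6 from 35.8 ± 3.11 to 71.2 ± 3.88 CPM. Their gene models in the table are long and can include reads of neighbouring histone genes. Of 16 Notch, Wnt and Hedgehog targets 5 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0230, adjusted p = 0.249 with an estimated correlation, and 0.0625 without DMSO replicate 3). The Notch target HEY1 fell 4.95-fold, from 13.7 ± 0.878 to 2.77 ± 0.397 CPM, and the Hedgehog transcription factor genes GLI1 and GLI2 fell by 1.73 and 0.69 on the log2 scale. HES1, another Notch target, did not pass (-0.30, adjusted p = 0.20). Immediate early genes and AP-1 members split: of 24, 9 fell and 8 rose, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.572). PHLDA1 (-0.51), the AP-1 gene FOSL1 (-0.88) and the MAP kinase phosphatase gene DUSP4 (-0.73) fell, whereas EGR1 (1.13), EGR3 (2.17) and FOS (1.59) rose.

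Metabolic and growth lists moved little or in both directions. Of 24 genes for cholesterol synthesis and uptake 6 fell, or 7 adjusted over the list alone, and 5 rose (camera adjusted p = 0.572); the synthase gene HMGCS1 fell by 0.67, the sigma-2 receptor gene TMEM97 by 0.38 and SQLE by 0.34 on the log2 scale. Of 20 hypoxia-inducible genes 5 rose, or 6 adjusted over the list alone, and 4 fell (camera direction up with adjusted p = 0.861, median 0.026 and mean -0.063). The glycolytic regulator PFKFB3 rose by 0.48, the glucose transporter gene SLC2A3 by 0.32 and NDRG1 by 0.27, and VEGFA fell by 0.72. In the list of NRF2 and aryl hydrocarbon receptor targets 4 of 16 genes rose, including CYP1B1 (0.32) and TIPARP (0.25), and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.861, median 0.0055 and mean -0.098). TIPARP lost its call without DMSO replicate 3 (adjusted p = 0.0545) or SGC-CBP30 replicate 2 (0.103). With the hepatic covariate the calls of TIPARP (0.296) and CYP1B1 (0.235) were lost. Among 20 genes of MYC and ribosome biogenesis NCL rose (0.17, adjusted p = 0.0464) and MYC fell (-0.21, adjusted p = 0.0380), none passed adjusted over the list alone, and camera's adjusted p was 0.985. Each call was lost in 5 of the 6 fits that left out a library, with adjusted p up to 0.145 for NCL and 0.140 for MYC, and with the replicate block (0.145 and 0.0985) and the hepatic covariate (0.718 and 0.715), and that of MYC with total counts alone (0.210). The 13 mitochondrially encoded mRNAs had 0 members past the edgeR threshold, 1 at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom (camera adjusted p = 0.831). The 22 cytosolic ribosomal protein genes had 0 past the edgeR threshold, 1 at an unadjusted p under 0.05, 1 with DESeq2 and 1 with limma-voom (camera adjusted p = 0.572).

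**Figure D3:**
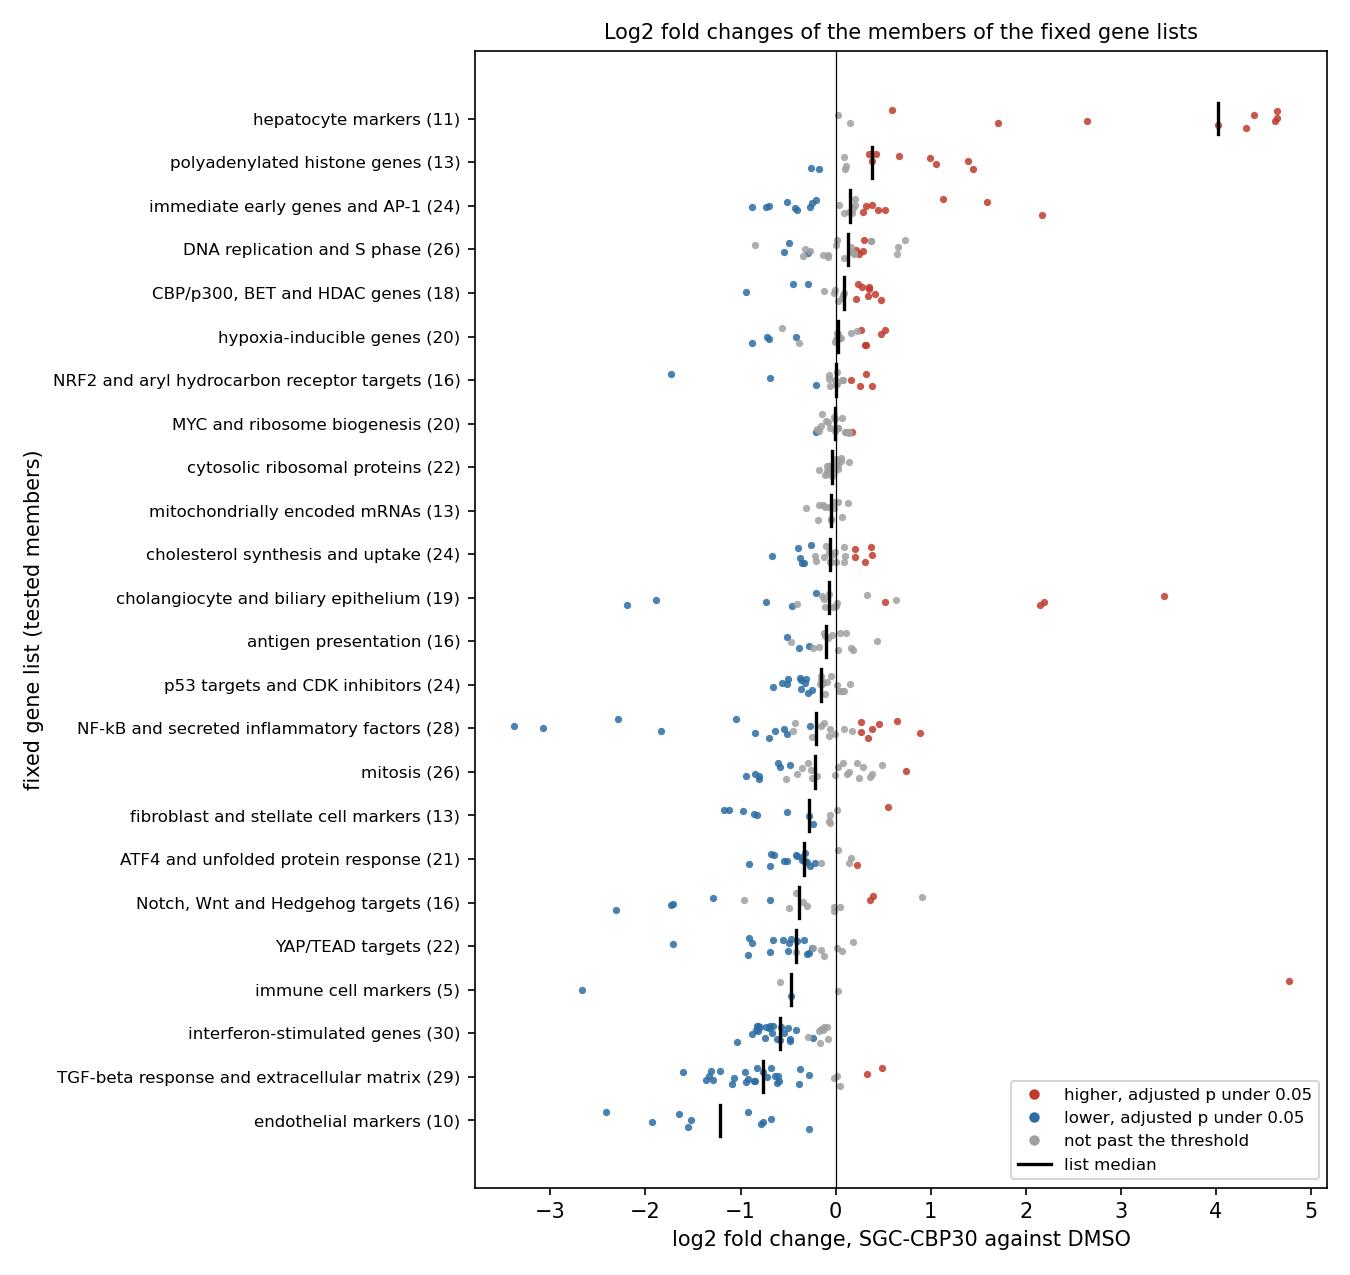
Log2 fold change (x axis) of each tested member of the 24 fixed lists (y axis, number of tested members in brackets), sorted by list median; red and blue points passed the threshold as higher or lower, grey points did not, and black bars are medians. The medians run from -1.22 for endothelial markers and -0.77 for the TGF-beta response and extracellular matrix to 4.02 for hepatocyte markers.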

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

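The covariate for hepatic transcripts and the count without genes high in SGC-CBP30 library 3 were chosen after the data were seen; the other alternatives were planned. Leaving out 1 library moved the 5207 genes changed to between 3784 (without SGC-CBP30 replicate 2) and 5473 (without DMSO replicate 3), the higher genes to between 1552 and 2533 and the lower genes to between 2232 and 2940. RLE scaling gave 5202 genes and shared 99.7% of the 5207, limma-voom 98.0% and DESeq2 89.4%. No filter gave 5571 genes and the edgeR exact test 5689. Total counts alone gave 6575 genes, 4384 of them higher, and the median log2 fold change of all tested genes went from 0.0053 to 0.098. A fold change of at least 2 left 992 genes (234 higher, 758 lower), and an adjusted p under 0.01 left 3225 (1264 higher), both by construction. The hepatic covariate left 1174 genes (383 higher, 791 lower); its values do not overlap between the groups (0.627 to 10.3 CPM in DMSO and 52.3 to 120 in SGC-CBP30), so it takes up part of the treatment term. Leaving out the genes high in SGC-CBP30 library 3 gave 5148. That count drops genes from the main fit without a new fit, so by construction it could only fall, and the lower genes stayed at 2893. The replicate numbers did not pair the samples: deviations from the group means correlated at -0.096, 0.014 and -0.096 for samples with the same number, and the samples did not all correlate best with their own number. With the replicate block 4148 genes passed, 1694 higher and 2454 lower, and no list changed its call. No list or named gene reversed its direction in any alternative where it was called. With an estimated correlation all 10 list calls were lost, with adjusted p = 0.249 (TGF-beta response and extracellular matrix, YAP/TEAD targets, Notch, Wnt and Hedgehog targets, fibroblast and endothelial markers), 0.251 (interferon, p53, ATF4 and histone lists) and 0.257 (hepatocyte markers). This setting allows for the members' correlation, estimated at 0.25 in the first list. The estimate was 0.0346 for the fibroblast list and -0.0435, below the preset 0.01, for the Notch, Wnt and Hedgehog list. Correlation of the members alone therefore does not account for every lost call. Camera's unadjusted p for the Notch, Wnt and Hedgehog list still went from 0.00958 to 0.0499. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the genes. Its smallest unadjusted p in this setting was 0.0396, for the fibroblast list. A call lost there is therefore not evidence that a list did not move. Fry, which does not compare a list with other genes, added the lists of CBP/p300, BET and HDAC genes (0.00775), NF-kB (0.00836), cholangiocyte (0.0187) and immune markers (0.0267). The hepatic covariate added the CBP/p300 list (0.0222), the NF-kB list (0.0198) and mitosis (0.00809). The NF-kB list also passed with total counts alone (0.0398) and without a filter (0.0469), where the Notch, Wnt and Hedgehog list did not (0.0709); the cause was not tested. Leaving out 1 library moved adjusted p between 0.0411 and 0.158 for the CBP/p300 list, 0.0429 and 0.182 for NF-kB, 0.0339 and 0.374 for mitosis, and 0.00886 and 0.0625 for the Notch, Wnt and Hedgehog list, each of which crossed the threshold in at least 1 such fit. Among the 82 named genes, DESeq2 lost 2 calls, limma-voom 1, the robust fit 2, total counts alone 3, the replicate block 4, and the hepatic covariate 30. The calls lost with that covariate include FN1 (adjusted p = 0.0655), HEXIM1 (0.0638) and CDKN1A (0.313), and not all of them are listed with the genes above. Leaving out a library lost between 1 and 7. Depth limits genes near 0.0558 to 0.0783 CPM (3 counts), such as several hepatic and epithelial genes in DMSO.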

Other observations

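The gene groups of the first 2 paragraphs and the tests on the induction of hepatic genes, on hepatic list members scarce in DMSO, on totals without the most abundant genes and on the spread of the fibroblast markers were chosen after the data were seen. The groups were put together from these values, so their p-values are not independent evidence that a group moved. A group of contractile genes, which also holds the matrix gene TNC and the cadherin gene CDH2, fell: of 18 measured genes 16 did, TNC and CDH2 among them (camera adjusted p = 1.78e-11 over 6 such groups, and adjusted p = 0.0401 with an estimated correlation). CNN1 (calponin) fell by 2.97 on the log2 scale, the enteric smooth muscle actin gene ACTG2 by 3.17, LMOD1 by 1.86 and the tropomyosin gene TPM1 by 1.07, while ACTN1 (0.10) and MYH11 (-0.095) did not pass. In a group of activin and BMP ligands, antagonists and target genes 9 of 15 fell and 1 rose (adjusted p = 2.45e-05, and adjusted p = 0.0778 with an estimated correlation). The BMP antagonist gene GREM1 fell 4.06-fold, from 1233 ± 68.5 to 303.5 ± 4.44 CPM, the activin subunit gene INHBA 3.76-fold and the activin antagonist gene FST by 1.07 on the log2 scale, and of the BMP targets ID1 rose by 0.91 while ID3 fell by 0.88 and ID4 by 1.28.

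In other groups more members rose. Of 22 lysosomal genes 13 rose by small amounts, such as CTSL (0.36) and NEU1 (0.41), or 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 3.30e-04, and adjusted p = 0.259 with an estimated correlation). Of 6 metallothioneins, which bind zinc and copper, 4 rose (adjusted p = 6.12e-04, and adjusted p = 0.106 with an estimated correlation), with MT2A going from 394.8 ± 23.0 to 718.3 ± 52.9 CPM and MT1X from 29.1 ± 2.72 to 65.1 ± 1.26 CPM. Of 16 neuronal cytoskeleton and vesicle genes 9 rose and 4 fell (adjusted p = 0.00571, and adjusted p = 0.0778 with an estimated correlation): TUBB3 rose by 1.38 and MAP6 by 1.66 on the log2 scale, and the neurofilament gene NEFL fell by 1.61. Retinoid pathway genes split, with 4 higher and 5 lower of 13, or 4 and 6 adjusted over the list alone (adjusted p = 0.224), among them CRABP2 (-1.96), STRA6 (-2.00) and RARRES1 (0.81).

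Hepatic transcripts were higher in all SGC-CBP30 libraries and in DMSO library 2, with ALB in SGC-CBP30 library 3 at 2.19 times the mean of libraries 1 and 2. If reads or RNA of another, hepatoma-like sample were the source, 22 other hepatic genes should show a like ratio; their summed CPM gave 1.01, below the limit of 1.3 set before it was seen, but C9, APOM, APOC1 and F10 made up 87.7% of that list's DMSO counts, so the limit was badly chosen for a small addition. Among the 15 members under 0.5 CPM in DMSO, a subset taken after that result, the ratio was 2.15 (1.64 at a limit of 1 CPM and 2.40 at 0.2 CPM). The source would also need DMSO library 2 raised. In that subset its CPM was 0.714 times the mean of DMSO libraries 1 and 3 (30 counts against 36 and 44). At the limit of 0.2 CPM the ratio was 0.829 (9 counts against 6 and 16). Only a small rise would be due, since DMSO library 2 had 166 ALB counts. SGC-CBP30 library 3 had 2337, and the subset held 183 counts there. The exact rise was not computed, and with so few counts these DMSO ratios decide nothing. Induction by SGC-CBP30 alone does not account for DMSO library 2, the 1 vehicle library at 2 or more times the lowest, but 1 library decides nothing. The 2 explanations cannot be told apart, because the test list was diluted and the excess follows the treatment. The subset was also picked from these values and held few counts in DMSO library 2.

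The cultures, labelled as biliary epithelial cells, held far more matrix than epithelial transcripts: in DMSO COL1A1 measured 28920 ± 3590 CPM and VIM 3313 ± 103 CPM, against 0.0953 ± 0.115 CPM for EPCAM. A small share of mesenchymal cells in an otherwise epithelial culture would leave epithelial junction genes abundant, but the highest median of 16 such genes in a DMSO library was 0.126 CPM, below the limit of 1 CPM set in advance. Keratins were not all low, with KRT18 at 210.0 ± 14.2 CPM and KRT8 at 153.2 ± 13.0 CPM. Beyond a mixed culture no explanation was tested, since both groups share the profile.

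The fall of the TGF-beta response and extracellular matrix list might come from scaling, since a few of its members are the most abundant transcripts. With the 20 most abundant genes left out before TMM scaling, the median log2 fold change of the 23 remaining members was -0.847, against -0.846 for the same members in the main fit; the median of all genes went from 0.0054 to 0.0042, so this step moved almost nothing and decides nothing. With the same genes left out of the totals under scaling by total counts, the median of all genes went from 0.0982 to 0.0422 and that of the 23 members from -0.752 to -0.808. The trend of log2 fold change on gene length lay between -0.00715 and 0.0139 at the lengths of the 29 members, far from their median of -0.766, which was -0.775 with the trend subtracted. Neither the most abundant transcripts in the totals nor gene length therefore accounts for the fall. A lower share of mesenchymal cells, acting alone, would lower their markers alike. The 13 fibroblast and stellate cell markers differed far beyond their errors (Cochran Q = 649 on 12 degrees of freedom), errors that reflect only the spread between these samples. This argues against a lower share as the only cause. It cannot exclude a lower share beside changes of single genes, which would also spread the markers. An effect of SGC-CBP30 on these genes stays open as a hypothesis. The estimated-correlation result (camera adjusted p = 0.249) concerns the list against other genes, whereas 24 of its 29 members fell in the gene-level test. For the count of 5207 changed genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split was the 1 split with as many, and the highest of the others gave 0 with edgeR (917 genes at an unadjusted p under 0.05, against 7360 for the real split). Every other split mixes both treatments in each group, so the treatment difference adds to the spread within its groups. Few calls were therefore bound to come from them, and the contrast does not measure chance.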
